A study of Mus musculus with 16 samples.

How the data were processed

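The series holds RNA sequencing of livers from mice of strain C57BL/6, 4 libraries in each of 4 groups: wild type on control diet, wild type after the Gao-Binge ethanol model, and both diets for mice labelled as liver-specific DRP1 knockouts. Per the labels' protocols, livers were snap frozen, total RNA was extracted with Trizol, and libraries from a standard Illumina protocol were sequenced as single reads of 75 bp on an Illumina instrument. Per the submitters' processing notes, HISAT2 2.1.0.13, HTSeq and edgeR were used with the mouse build GRCm38; the annotation release, the strand setting and which tool made the size factors are not given in the sources used here. Without a stated strand setting, reads of a gene and its antisense partner cannot be told apart, and members of families with near-identical copies are uncertain.

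The deposited table holds a signal per gene and library, read counts that the authors divided by 1 size factor per library. In each library the values are whole multiples of 1 step, and 100% of them came out whole within 0.01 of a read, so whole reads were recovered. The recovered size factors, 0.81 to 1.26, differed from median-of-ratios factors computed on these genes by at most 1.5e-10, so the planned rescaling by such factors changes nothing and was not run. Depth was 11425136 to 13864862 reads per library. Of 27288 gene identifiers 27233 were matched to a symbol and to coordinates of GENCODE on GRCm38, and 55 were not. No 2 libraries of a group agreed within sampling noise, with a mean chi-square per gene from 11.1 to 121 between replicates, so each counted as 1 sample.

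Comparisons used limma 3.58.1 in R 4.3.3 on log2(value + 1), for the 13256 genes with a mean value of at least 10 over the 16 libraries, in 1 fit of 4 group means with a mean-variance trend and 5 contrasts: genotype on each diet, ethanol in each genotype, and the difference of the ethanol effects. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Fold changes are on the scale of value + 1, which understates changes of low genes. Every adjusted p for a gene is from limma. The 49 gene lists were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, two-sided, adjusted over the lists within a contrast; the count of members past the threshold is given over all genes and adjusted over the list alone. With an estimated correlation, the calls that held were those of the interferon-stimulated, antigen presentation and DNA sensing lists for the genotype on both diets, and of the pericentral list for the genotype on ethanol. Dnm1l was also tested by exact two-sided permutation on each diet.

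Genes named were Dnm1l and those taken by a rule fixed before the data were examined: per contrast the 6 largest rises and 6 largest falls among called genes with a mean log2 value above the median gene whose groups do not overlap (no such condition for the difference of the ethanol effects), predicted genes left out, and for each list with 3 or more called members up to 3 with the smallest p. Not every gene the rule takes is named, and which of them are named was chosen after their values were seen; 3 that were to be named are not reported here. Outside the rule are the sex-linked and tissue marker genes Ddx3y, Xist, Ctrb1, Prss2, Cpa1, Cfd, Adipoq, Hba-a1 and Saa1, and Cx3cr1, Orm3 and Ifi27l2a for the difference of the ethanol effects, which were chosen after their values were seen.

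Same-numbered libraries were compared by the correlation of their deviations from the group means across genes. Between the ethanol groups every pair was above 0.1, from 0.102 to 0.246, so for the genotype on ethanol the numbers were read as pairing the libraries from the data alone, since the labels do not say what a number marks. Libraries with other numbers correlated at 0.1 to 0.2 within libraries 1 and 2 and within 3 and 4, and at -0.25 to -0.08 between these sets, so the shared deviation cannot be assigned to the numbers rather than to the sets. Alternatives were pseudocounts of 0.25 and 4, no filter, a floor of 50, no trend, only the groups compared, the replicate number as a block, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads. On those reads edgeR called 1525, 1281, 5013, 2679 and 30 genes and DESeq2 1924, 1704, 5150, 3028 and 270 for the 5 contrasts in the order above. Chosen after seeing the data were TMM factors, the ethanol groups without libraries 1 and 4 labelled knockout, libraries 1 and 2 or 3 and 4 of the ethanol groups alone, and a block in the ethanol groups only.

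The limma functions were tested on simulated counts for 13256 genes with the overall means, dispersions and library sizes of these data. In them 200 genes were changed, and a further list of genes was raised together by 1.5-fold. Libraries were drawn independently, without the difference between libraries 1 and 2 and libraries 3 and 4 of the ethanol groups. Far fewer genes were changed than were called in most real contrasts, so the shares hold for these settings. Of genes changed 4-fold, 93.9% were recovered for the genotype on control diet, 97% for the genotype on ethanol, 93.9% for ethanol in wild type, 98.5% for ethanol in the libraries labelled knockout and 81.8% for the difference of the ethanol effects; of genes changed 2-fold the shares were 62.7%, 64.2%, 71.6%, 61.2% and 26.9%. At most 7 of 13036 unchanged genes were called in a comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.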

Results

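RNA was sequenced from livers of C57BL/6 mice labelled as liver-specific knockouts of DRP1, the mitochondrial fission GTPase encoded by Dnm1l, and of wild-type mice. Each genotype was studied on a control condition and in the Gao-Binge model, in which feeding of an ethanol diet ends with a single high dose of ethanol; the control is called control diet here. The 4 groups held 4 libraries each, 16 in all, and the question was what loss of hepatic DRP1 changes with and without ethanol. Each library held between 11425136 and 13864862 reads assigned to genes, and 13256 of 27288 genes were tested. All 16 libraries had the expression pattern of male mice, with Ddx3y between 1023 and 2107 normalised reads and Xist at 9.3 or below. The labels give each library as a separate sample of its group and do not say that each came from its own mouse, so the p-values measure the spread between these samples.

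Dnm1l itself was not called different between the genotypes on either diet. The gene (ENSMUSG00000022789, chromosome 16, 16312230 to 16358959 in GRCm38) had 642 ± 72.7 normalised reads (SD, n = 4) in the control-diet libraries labelled knockout and 663 ± 56.2 in the wild-type ones, a fold of 0.967 with a 95% interval from 0.828 to 1.13. On ethanol the values were 803 ± 99.3 and 743 ± 38.4 (SD, n = 4), a fold of 1.08 with an interval from 0.922 to 1.26. Exact two-sided permutation tests of 4 against 4 gave p = 0.571 on control diet and p = 0.343 on ethanol, where the smallest p possible is 0.0286. The ethanol test did not pair the libraries by number. Limma gave a log2 fold change of -0.05 ± 0.11 (SE, adjusted p = 0.825) on control diet and 0.11 ± 0.11 (SE, adjusted p = 0.590) on ethanol. Each library held between 584 and 929 recovered reads of the gene. With ethanol, Dnm1l rose 1.25-fold in the libraries labelled knockout (log2 0.32 ± 0.11 SE, limma adjusted p = 0.0421). That call was lost without any 1 of wild-type control libraries 1, 3 and 4, control libraries 1, 2 and 3 labelled knockout, or ethanol libraries 1, 2 and 4 labelled knockout (log2 0.24 to 0.35, adjusted p from 0.0503 to 0.142). It was also lost without a filter, without the trend, with only the groups compared and with the replicate block (adjusted p = 0.0805, 0.0594, 0.0867 and 0.0556), and without ethanol libraries 1 and 4 labelled knockout or with ethanol libraries 3 and 4 alone (adjusted p = 0.0998 and 0.266). The values are totals per gene, a deletion of some exons can leave reads over the others, and the labels do not say which part was deleted. The gene total therefore gives no check of the genotype labels, and each direction below holds for libraries as labelled.

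**Figure D1:**
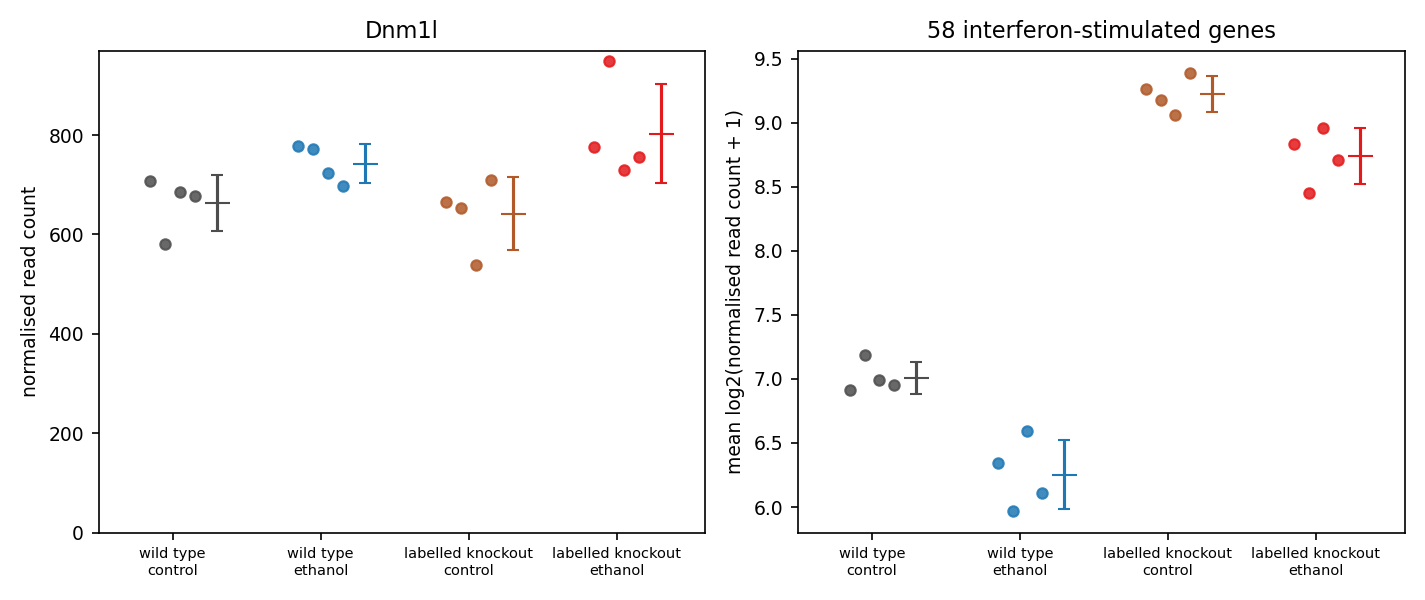
Left, normalised read count of Dnm1l in each library; right, mean log2(normalised read count + 1) of the 58 measured interferon-stimulated genes. Points are the 4 libraries of each group, and the bar beside them is the mean with its SD. Dnm1l lies between 538.6 and 949.1 over all libraries, while the interferon-stimulated mean lies between 8.45 and 9.39 in the libraries labelled knockout and between 5.97 and 7.19 in the wild-type ones.

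On control diet, the libraries labelled knockout were set apart by interferon-stimulated genes. Of the 58 measured members of that list, 55 rose, 57 adjusted over the list alone, none fell, and the median log2 fold change was 1.89 (limma camera adjusted p = 2.69e-69, and adjusted p = 0.00921 with an estimated correlation). Isg15, a ubiquitin-like antiviral protein (ENSMUSG00000035692, chromosome 4, 156199424 to 156200818), went from 84.0 ± 8.18 to 1094 ± 183 normalised reads (SD, n = 4), a 12.8-fold rise (log2 3.68 ± 0.18 SE, limma adjusted p = 1.14e-09). Oasl2 rose 21.5-fold and Rsad2, which encodes the antiviral enzyme viperin, 15.8-fold. Ly6a (ENSMUSG00000075602, chromosome 15, 74994877 to 74998031), which encodes the surface antigen Sca-1, rose 31.7-fold, from 79.3 ± 43.7 to 2569 ± 1264. Antigen presentation genes followed, with 16 of 21 higher, 20 adjusted over the list alone, and none lower (camera adjusted p = 1.82e-20, and adjusted p = 0.0385 with an estimated correlation). Among them the immunoproteasome subunit Psmb8 rose 2.80-fold and the class I heavy chain H2-D1 2.71-fold. In the list of cytosolic DNA sensors and inflammasome genes, 7 of 19 rose and 1 fell, 11 and 1 adjusted over the list alone (camera adjusted p = 1.21e-05, and adjusted p = 0.0385 with an estimated correlation). Its members Irf7, the transcription factor that amplifies the type I interferon response, and Zbp1, a sensor of Z-form nucleic acids, rose 8.91-fold and 5.96-fold. Irf7 is also on the interferon-stimulated list, so the results of these lists are not independent.

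Leukocyte markers were also higher in these control-diet libraries. Of 17 Kupffer cell and macrophage markers 10 rose and 1 fell, 15 and 1 adjusted over the list alone (camera adjusted p = 1.16e-08, but adjusted p = 0.240 with an estimated correlation). The groups overlapped in the mean log2 value of this list. Wild-type control library 2 had 8.253, against 6.972 to 7.305 in the others of its group and 7.927 to 8.557 in the libraries labelled knockout. Mpeg1, which encodes the pore-forming protein perforin-2 of phagocytes, went from 860 ± 341 to 3716 ± 1259 normalised reads (SD, n = 4). Of the inflammation list 11 of 23 members rose, 13 adjusted over the list alone, and none fell (camera adjusted p = 1.16e-08, but adjusted p = 0.0550 with an estimated correlation). The chemokine genes Cxcl9 and Ccl5 rose 6.23-fold and 12.6-fold. Endothelial and stellate cell lists were not past the threshold (camera adjusted p = 0.990 and 0.800), with 1 lower gene each of 18 and 17. Of 29 proliferation genes 7 rose, 14 adjusted over the list alone, with a median log2 fold change of 0.89 (camera adjusted p = 2.62e-08, but adjusted p = 0.232 with an estimated correlation). Mki67, a marker of cycling cells, was 3.23-fold higher (limma adjusted p = 0.0168). That call was lost without wild-type control library 3 or control library 4 labelled knockout (adjusted p = 0.0516 and 0.0501).

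Genes of the NRF2 antioxidant response made up the next group on control diet, with 16 of 29 higher, 17 and 1 lower adjusted over the list alone (camera adjusted p = 8.12e-12, but adjusted p = 0.0929 with an estimated correlation). Nqo1, a quinone reductase (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206), rose from 61.9 ± 9.43 to 217 ± 47.8 normalised reads (SD, n = 4). The carbonyl reductase gene Cbr3 rose 57.4-fold, to 338 ± 280. The cystine transporter gene Slc7a11 was at 0 in 3 of the 4 wild-type libraries and at 45.0 ± 16 (SD, n = 4) in the libraries labelled knockout. Of 18 p53 targets 6 rose, 10 adjusted over the list alone (camera adjusted p = 4.52e-05, but adjusted p = 0.0581 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose 7.16-fold and Mdm2 1.54-fold. Of 27 genes of the integrated stress response 7 rose and 1, Vldlr, fell, 11 and 1 adjusted over the list alone (camera adjusted p = 5.03e-05, but adjusted p = 0.368 with an estimated correlation).

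Transcripts encoded by mitochondrial DNA were lower in the control-diet libraries labelled knockout, with 4 of 11 past the threshold and 6 adjusted over the list alone (camera adjusted p = 3.95e-05, but adjusted p = 0.232 with an estimated correlation). The cytochrome b transcript mt-Cytb had 59510 ± 10250 normalised reads against 118100 ± 11960 in wild type (SD, n = 4). Of 23 lipogenesis genes 6 fell, 11 adjusted over the list alone where 1 more was higher (camera adjusted p = 4.52e-05, but adjusted p = 0.370 with an estimated correlation), including the desaturases Fads1 and Scd1 at folds of 0.536 and 0.371. The Scd1 call was lost without wild-type control library 3 or control library 3 labelled knockout (limma adjusted p = 0.0597 and 0.0571). Wild-type control library 3 had a mean log2 value of 12.55 over the lipogenesis list, against 11.48 to 11.57 in the others of its group. The control-diet libraries labelled knockout had 10.96 to 11.55. Fatty acid oxidation genes fell for 6 of 27, 8 adjusted over the list alone (camera adjusted p = 0.000124, but adjusted p = 0.415 with an estimated correlation). Ppara, the nuclear receptor that drives many of them, was at a fold of 0.469, and the carnitine palmitoyltransferase gene Cpt1a at 0.730. Of 19 pericentral markers 7 fell and 3 rose, both over all genes and adjusted over the list alone (camera adjusted p = 0.0314, but adjusted p = 0.240 with an estimated correlation). Without any 1 of wild-type control libraries 2 and 3 or control library 3 labelled knockout, or at a floor of 50, the call of this list was lost (adjusted p = 0.0576, 0.0691, 0.120 and 0.0572). Of these markers the glutamate transporter Slc1a2 was at a fold of 0.362, while Cyp2a5 was 3.97-fold higher. Cyp2c37, of the list of xenobiotic cytochrome P450 genes, was at a fold of 0.317. Cyp2a5 is on that list too, and its member Cyp2b10 rose from 5.07 ± 4.11 to 42.3 ± 24.9 normalised reads (SD, n = 4). The mean log2 value of that list was 8.475 to 9.283 in these libraries, overlapping 8.542 to 8.918 in wild type.

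Over all genes on control diet, limma called 1544 at an adjusted p under 0.05, of which 849 were higher and 695 lower in the libraries labelled knockout. At least a 2-fold change was seen for 421 of the higher and 160 of the lower genes. The count was 922 without wild-type control library 4.

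On ethanol, interferon-stimulated genes again separated the genotypes. As on control diet, 55 of 58 were higher in the libraries labelled knockout, 57 adjusted over the list alone, with a median log2 fold change of 2.08 (camera adjusted p = 1.91e-77, and adjusted p = 0.00561 with an estimated correlation). Isg15 had 600.5 ± 148 normalised reads against 28.6 ± 4.22 in wild type (SD, n = 4), a 19.9-fold difference (log2 4.32 ± 0.18 SE, limma adjusted p = 8.18e-11). Ifi44 was 41.6-fold, Rsad2 25.4-fold and Irf7 17.2-fold higher. Antigen presentation genes were higher for 19 of 21, 20 adjusted over the list alone (camera adjusted p = 5.37e-22, and adjusted p = 0.0301 with an estimated correlation). DNA sensing and inflammasome genes were higher for 7 of 19, 9 adjusted over the list alone where 1 was lower (camera adjusted p = 2.77e-05, and adjusted p = 0.0366 with an estimated correlation). Irf7 counts in this list as well as in the interferon-stimulated one. Of 17 Kupffer cell and macrophage markers 16 were higher, again 16 and 1 lower adjusted over the list alone (camera adjusted p = 1.44e-19, but adjusted p = 0.0871 with an estimated correlation). Mpeg1 was 7.80-fold, the lysozyme gene Lyz2 4.64-fold and the complement subunit gene C1qb 4.01-fold higher. Of 15 markers of monocyte-derived cells 9 were higher and 1 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 6.57e-06, but adjusted p = 0.0886 with an estimated correlation). The lipid-associated macrophage receptor Trem2 was at 26.7 ± 8.94 against 2.21 ± 2.13 normalised reads (SD, n = 4). Fibrosis genes were higher for 9 of 25, 12 adjusted over the list alone (camera adjusted p = 7.67e-08, but adjusted p = 0.152 with an estimated correlation). The collagen genes Col1a1 and Col5a2 were 2.95-fold and 2.71-fold higher. Of 29 proliferation genes 14 were higher, 20 adjusted over the list alone, with Ccna2, a cyclin of S phase, at 3.34-fold (camera adjusted p = 5.49e-08, but adjusted p = 0.152 with an estimated correlation). At a floor of 50, which leaves out low members, the calls of the monocyte and proliferation lists were lost, with medians of -0.06 and -0.13 (adjusted p = 0.546 and 0.935).

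Pericentral and drug-metabolising genes were lower in the ethanol libraries labelled knockout. Of 19 pericentral markers 7 were lower, 10 adjusted over the list alone, and none higher (camera adjusted p = 2.82e-06, and adjusted p = 0.0301 with an estimated correlation). Glul, the glutamine synthetase gene of the hepatocytes next to the central vein, was at a fold of 0.467, Slc1a2 at 0.379 and Lhpp at 0.383. Of 24 xenobiotic cytochrome P450 genes 12 were lower, 15 adjusted over the list alone (camera adjusted p = 5.49e-08, but adjusted p = 0.0871 with an estimated correlation). Cyp2c37 (ENSMUSG00000042248, chromosome 19, 39992424 to 40012243) had 1327 ± 395 normalised reads against 8618 ± 1156 (SD, n = 4), Cyp2c29 was at a fold of 0.258 and the retinoic acid hydroxylase Cyp26a1 at 0.126. The Cyp2a, Cyp2c, glutathione transferase, Mup and class I families hold near-identical copies, so how their reads were divided between members is uncertain. Of 11 transcripts encoded by mitochondrial DNA 7 were lower, 8 adjusted over the list alone, with mt-Cytb at a fold of 0.484 (camera adjusted p = 1.17e-07, but adjusted p = 0.0950 with an estimated correlation). Reads over protein-coding genes of mitochondrial DNA made up 3.73 ± 0.124% of the library against 5.01 ± 0.305% in wild type (SD, n = 4), and 2.80 ± 0.373% against 3.74 ± 0.158% on control diet. Of 18 hepatocyte markers 3 were lower, 5 and 1 higher adjusted over the list alone, with a median log2 fold change of -0.28 (camera adjusted p = 0.000239, but adjusted p = 0.152 with an estimated correlation). On control diet 2 of them were lower, 5 adjusted over the list alone, with a median of -0.29 (camera adjusted p = 0.000375, but adjusted p = 0.232 with an estimated correlation). Of 29 NRF2 targets 2 were higher and 1 lower on ethanol, 2 and 2 adjusted over the list alone. Their median log2 fold change was -0.09 while the mean was 0.15 and the test pointed up (camera adjusted p = 0.938).

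Limma called 1310 genes between the genotypes on ethanol, 813 higher and 497 lower in the libraries labelled knockout, with at least a 2-fold change for 504 and 95. Ethanol library 1 labelled knockout held pancreas transcripts (Ctrb1 at 2563 normalised reads against 5 or fewer in the other libraries) and library 4 blood transcripts (Hba-a1 at 1506 against 418 or fewer). Both held reads of the fat gene Adipoq, at 10 and 18 against 0 in the others. The fat gene Cfd was high in library 4, at 120, but not in library 1, at 18 against up to 69 in wild-type control libraries. Libraries 1 and 2 differed from 3 and 4 in both ethanol groups. The count was 496 without libraries 1 and 4 labelled knockout, 979 with libraries 1 and 2 of both groups, 434 with libraries 3 and 4, 857 without wild-type ethanol library 1 and 848 without ethanol library 3 labelled knockout. With libraries 3 and 4 alone Col5a2, Ccna2, Cyp26a1 and mt-Cytb were not called (log2 1.542, 1.611, -2.75 and -0.938, against 1.44, 1.74, -2.99 and -1.05 with all libraries), nor was Col5a2 with libraries 1 and 2 alone (1.335); the interferon-stimulated median was 2.12 to 2.17 in the fits of the subsets.

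**Figure D2:**
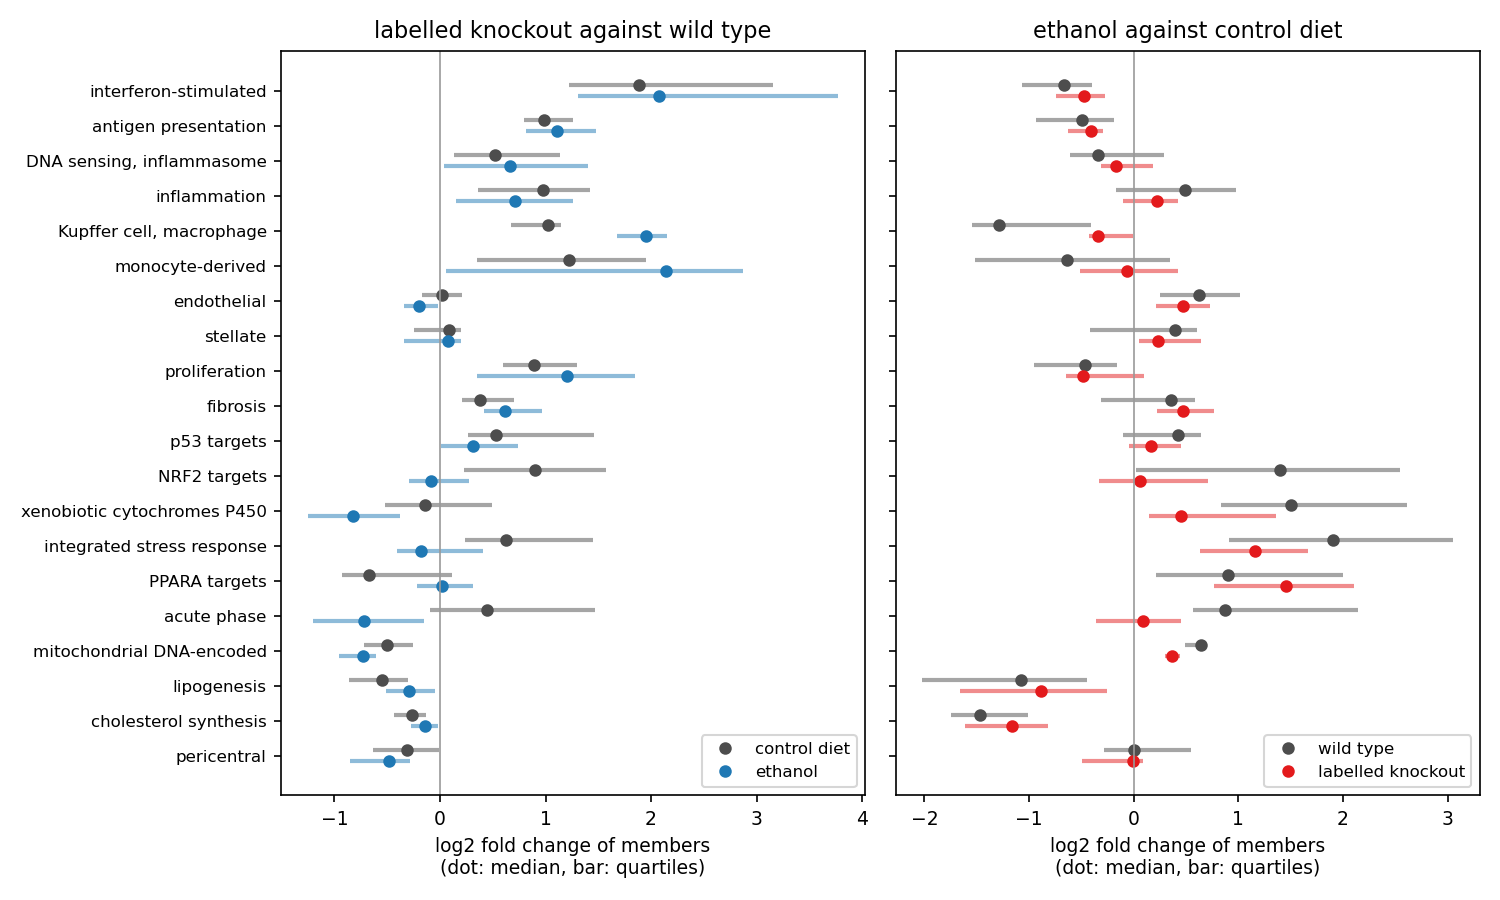
Log2 fold changes of the members of 20 gene lists, with the dot at the median and the bar from the lower to the upper quartile of the members; left, libraries labelled knockout against wild type on each diet; right, ethanol against control diet in each genotype. The interferon-stimulated medians are 1.89 and 2.08 on the left and -0.67 and -0.47 on the right.

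Across the 13256 genes, which are not independent replicates, the genotype effects on control diet and on ethanol, taken from separate libraries, had a Pearson correlation of 0.599 and a Spearman correlation of 0.386. The Pearson value was 0.557 without the interferon-stimulated list. Of the called genes 399 were higher on both diets, where independent lists would share 52.1, and 150 were lower on both, against 26.1. Opposite directions were called for 3 genes.

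**Figure D3:**
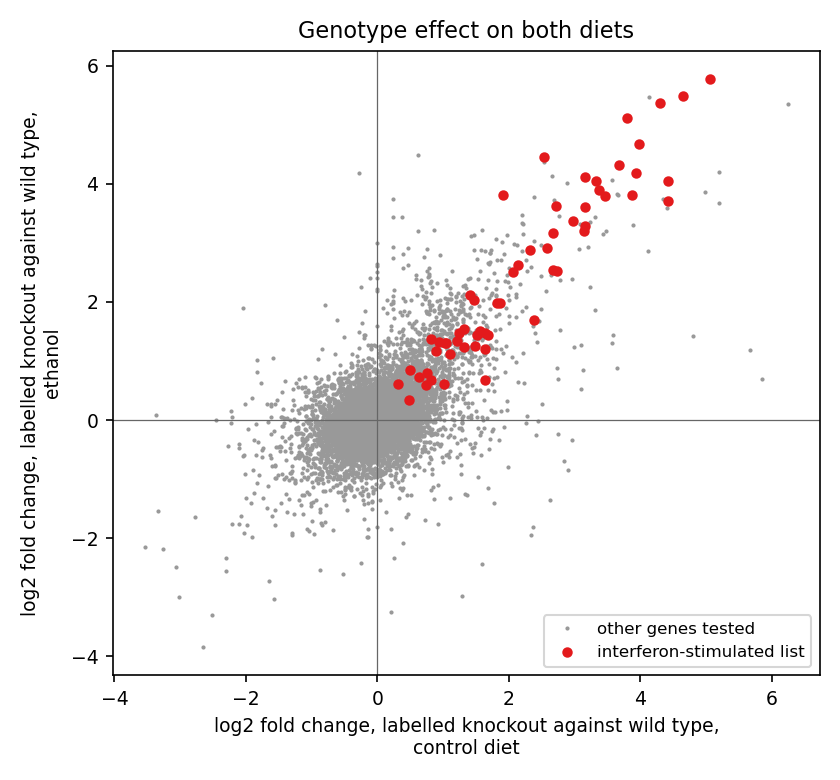
Log2 fold change of each tested gene between libraries labelled knockout and wild-type libraries, on control diet (x axis) and on ethanol (y axis). Red points are the 58 interferon-stimulated genes, and the Pearson correlation over all 13256 genes is 0.599.

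Ethanol in wild-type livers raised drug-metabolism, stress and acute-phase genes. Of 24 xenobiotic cytochrome P450 genes 19 rose, 21 adjusted over the list alone, and none fell (camera adjusted p = 4.95e-09, but adjusted p = 0.327 with an estimated correlation). Cyp2b10, the classical target of the nuclear receptor CAR (ENSMUSG00000030483, chromosome 7, 25897620 to 25926624), went from 5.07 ± 4.11 to 16940 ± 1957 normalised reads (SD, n = 4; log2 11.67 ± 0.42 SE on the scale of value + 1, limma adjusted p = 1.89e-11). Cyp2a5 rose 7.12-fold and the P450 reductase Por 3.97-fold. Of 27 genes of the integrated stress response 22 rose, 25 adjusted over the list alone, and none fell, past the threshold (camera adjusted p = 2.29e-10, but adjusted p = 0.354 with an estimated correlation). The mitochondrial folate enzyme Mthfd2 rose 8.59-fold and the amino acid transporter subunit Slc3a2 3.17-fold. The serine synthesis enzyme Psat1 rose by 3.70 ± 0.36 on the log2 scale (SE, limma adjusted p = 1.59e-06). Of 29 NRF2 targets 17 rose and 4 fell, the same numbers as adjusted over the list alone (camera adjusted p = 8.12e-06, but adjusted p = 0.430 with an estimated correlation). Gstm3 rose 25.6-fold, Abcc4 21.3-fold and Nqo1 3.74-fold. Cdkn1a rose from 15.2 ± 5.63 to 2308 ± 1574 normalised reads and the metallothionein gene Mt2 from 37.8 ± 27.2 to 15320 ± 11090 (SD, n = 4). Of 28 acute-phase genes 11 rose and 1 fell, also adjusted over the list alone, with Lcn2 at 18340 ± 15620 against 194 ± 135 (camera adjusted p = 0.000846, but adjusted p = 0.704 with an estimated correlation). Lcn2 had 35294 and 27073 in ethanol libraries 1 and 2 and 1136 and 9839 in libraries 3 and 4, and the call of the list was lost with libraries 3 and 4 alone (adjusted p = 0.363). PPARA targets rose for 11 of 19 and fell for 2, also adjusted over the list alone, with the lipid droplet protein Cidec going from 59.0 ± 14.7 to 1225 ± 466 normalised reads (SD, n = 4) and the thioesterase Acot2 at 6.11-fold (camera adjusted p = 0.00138, but adjusted p = 0.430 with an estimated correlation). Endothelial markers rose for 11 of 18 and fell for 1, 12 and 1 adjusted over the list alone, including the VEGF receptor Flt1, 3.47-fold, and Lyve1, 7.52-fold (camera adjusted p = 8.46e-05, but adjusted p = 0.430 with an estimated correlation).

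Lipid synthesis and immune genes fell with ethanol in wild type. Of 24 cholesterol synthesis genes 18 fell, 20 adjusted over the list alone (camera adjusted p = 1.98e-08, but adjusted p = 0.430 with an estimated correlation). Of 23 lipogenesis genes 17 fell, 17 adjusted over the list alone where 1 rose (camera adjusted p = 1.01e-05, but adjusted p = 0.430 with an estimated correlation). The sterol sensor Insig1 was at a fold of 0.158, the transcription factor Srebf1 at 0.152 and Fasn, fatty acid synthase, at 0.240. Interferon-stimulated genes fell for 40 of 58 and 1 rose, 45 and 3 adjusted over the list alone, with a median log2 fold change of -0.67 (camera adjusted p = 3.27e-09, but adjusted p = 0.430 with an estimated correlation). Isg15 was at a fold of 0.346 and Ifi44 at 0.187. Kupffer cell and macrophage markers fell for 12 of 17, also adjusted over the list alone, with Cd5l at a fold of 0.247 and Vsig4 at 0.291 (camera adjusted p = 6.61e-06, but adjusted p = 0.430 with an estimated correlation). Complement and coagulation genes fell for 14 of 26 and 1 rose, 15 and 1 adjusted over the list alone, with C9 at a fold of 0.386 and C6 at 0.223 (camera adjusted p = 0.000367, but adjusted p = 0.430 with an estimated correlation).

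In wild type, limma called 5032 genes for ethanol, 2508 higher and 2524 lower, with at least a 2-fold change for 798 and 833. The count was 3164 with only libraries 3 and 4 of the ethanol groups.

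In the libraries labelled knockout, ethanol again lowered lipid synthesis genes and raised PPARA targets and stress genes. Cholesterol synthesis genes fell for 16 of 24, 20 adjusted over the list alone (camera adjusted p = 9.51e-11, but adjusted p = 0.418 with an estimated correlation). Lipogenesis genes fell for 13 of 23, 15 adjusted over the list alone where 1 rose (camera adjusted p = 5.78e-06, but adjusted p = 0.418 with an estimated correlation). Fasn (ENSMUSG00000025153, chromosome 11, 120805846 to 120824547) went from 19160 ± 1120 to 4332 ± 290 normalised reads (SD, n = 4), and the citrate lyase gene Acly was at a fold of 0.185. PPARA targets rose for 13 of 19 and fell for 1, 16 and 1 adjusted over the list alone (camera adjusted p = 1.41e-08, but adjusted p = 0.311 with an estimated correlation), with Cidec at 18.8-fold, Acot2 at 7.05-fold and the lipid droplet coat protein Plin2 at 2.94-fold. Genes of the integrated stress response rose for 14 of 27 and fell for 1, 19 and 1 adjusted over the list alone (camera adjusted p = 3.00e-08, but adjusted p = 0.418 with an estimated correlation), with Vldlr, from 6.77 ± 3.11 to 60.6 ± 14.1 normalised reads (SD, n = 4), and Nupr1 at 3.34-fold. Xenobiotic cytochrome P450 genes rose for 7 of 24, 10 adjusted over the list alone (camera adjusted p = 0.000104, but adjusted p = 0.418 with an estimated correlation). Cyp2b10 went from 42.3 ± 24.9 to 10090 ± 3742. Interferon-stimulated genes fell for 23 of 58 and 1 rose, 29 and 1 adjusted over the list alone (camera adjusted p = 7.36e-08, but adjusted p = 0.418 with an estimated correlation), with Oasl2 at 587 ± 153 normalised reads after ethanol against 1485 ± 510 on control diet (SD, n = 4). Endothelial markers rose for 8 of 18, 9 adjusted over the list alone, with Lyve1 at 4.91-fold (camera adjusted p = 0.000207, but adjusted p = 0.418 with an estimated correlation).

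Limma called 2543 genes for ethanol in the libraries labelled knockout, 1348 higher and 1195 lower, with at least a 2-fold change for 450 and 239. The count was 1003 without ethanol libraries 1 and 4 labelled knockout and 1370 with only libraries 3 and 4 of the ethanol groups.

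The ethanol effects in the genotypes, from separate libraries, had a Pearson correlation of 0.767 and a Spearman correlation of 0.716 across 13256 genes, which are not independent replicates. Of the called genes 1057 rose in both, against 255 for independent lists, 903 fell in both, against 227.5, and 5 were called in opposite directions.

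**Figure D4:**
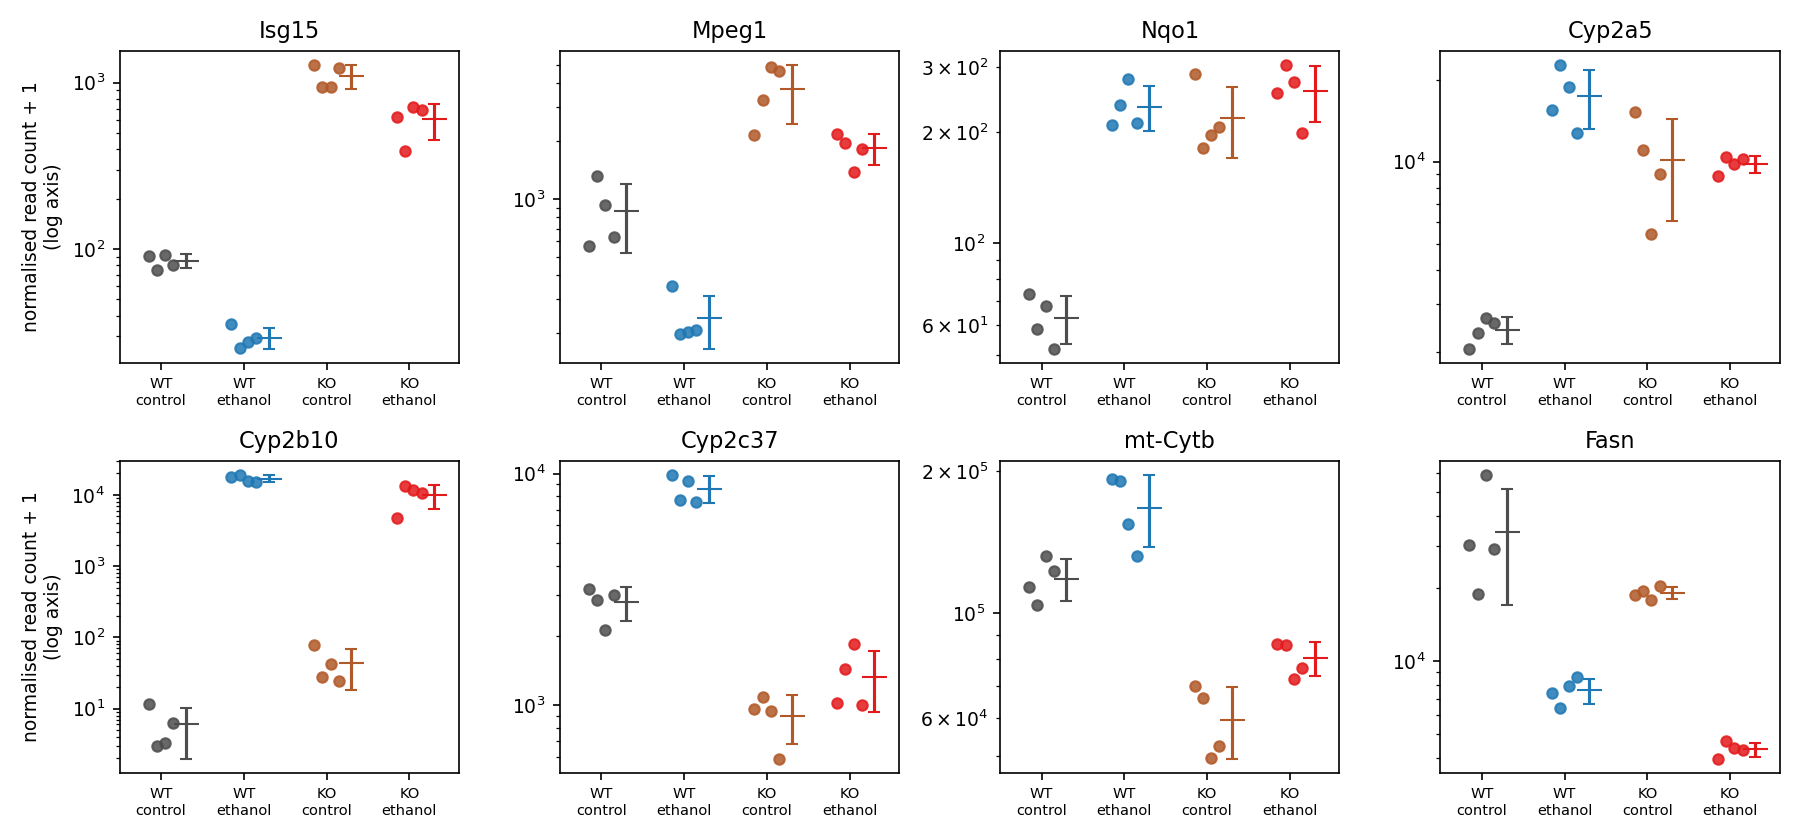
Normalised read count + 1 of 8 genes in each library, on a log axis; WT is wild type and KO the libraries labelled knockout, points are the 4 libraries of each group and the bar beside them is the mean with its SD. Isg15 lies higher in the libraries labelled knockout on both diets, Fasn lower after ethanol in both genotypes, and Cyp2a5 has means of 10180 and 9818 in the libraries labelled knockout on control diet and ethanol against 2406 and 17440 in wild type.

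The ethanol response differed between the genotypes for detoxification genes by limma's test of the difference. Of 29 NRF2 targets 6 had a lower ethanol response in the libraries labelled knockout, 16 adjusted over the list alone, with a median difference of -0.90 in log2 fold change (camera adjusted p = 2.59e-13, but adjusted p = 0.318 with an estimated correlation). Nqo1 went from 61.9 ± 9.43 to 233 ± 32.5 normalised reads with ethanol in wild type and from 217 ± 47.8 to 257 ± 44.2 in the libraries labelled knockout (SD, n = 4; difference -1.65 ± 0.24 SE, limma adjusted p = 0.0105). Abcc4 and Cbr3 had differences of -2.16 ± 0.31 and -5.15 ± 0.78 (SE, limma adjusted p = 0.0105 and 0.0116). Of 24 xenobiotic cytochrome P450 genes 2 had a lower response, 6 adjusted over the list alone (camera adjusted p = 3.34e-07, but adjusted p = 0.318 with an estimated correlation). Cyp2a5 rose from 2406 ± 271 to 17440 ± 4290 in wild type and had 10180 ± 4113 and 9818 ± 698 normalised reads on control diet and ethanol in the libraries labelled knockout (SD, n = 4; difference -2.79 ± 0.33 SE, limma adjusted p = 0.00264). Cyp2b10 differed by -3.74 ± 0.59 (SE, limma adjusted p = 0.0147). Further genes with a lower response were Cdkn1a, Gsta2, Gstm3 and Cyp26a1, at differences from -4.28 to -2.66. All of these already had higher means on control diet in the libraries labelled knockout. On ethanol Gstm3 and Gsta2 had means of 5040 and 443 there, against 6041 and 522 in wild type. Cdkn1a and Cyp26a1 had 1298 and 177 against 2308 and 1266. Pltp, C6, Ppara, Lyz2 and Elovl2 had differences from 1.31 to 1.89. Their means fell with ethanol in wild type and fell less or not at all in the libraries labelled knockout. For Ppara they went from 1592 to 572 against 768 to 772. With the replicate number as a block the calls of Cdkn1a, Cyp26a1, Pltp, C6, Ppara and Lyz2 were lost (adjusted p = 0.0561, 0.0739, 0.0564, 0.0739, 0.0564 and 0.0646). Of 17 Kupffer cell and macrophage markers 1 had a higher response, 9 adjusted over the list alone, with a median difference of 0.83 (camera adjusted p = 1.44e-07, but adjusted p = 0.843 with an estimated correlation).

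For this difference limma called 46 genes, 19 higher and 27 lower, and edgeR and DESeq2 on recovered reads called 30 and 270. The count lay between 8 and 215 when single libraries were left out, and was 24 with the replicate number as a block, 0 without ethanol libraries 1 and 4 labelled knockout, 264 with libraries 1 and 2 of the ethanol groups and 0 with libraries 3 and 4. No named gene kept its call throughout, but without ethanol libraries 1 and 4 labelled knockout the differences of Cyp2a5, Cbr3, Cyp2b10, Abcc4 and Nqo1 were -2.748, -5.033, -3.332, -1.897 and -1.474, and with libraries 3 and 4 they were -2.619, -4.747, -3.357, -1.951 and -1.844. Without ethanol libraries 1 and 4 labelled knockout 1210 genes had an unadjusted p under 0.05 and edgeR called 0, and with libraries 3 and 4 the numbers were 925 and 5.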

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

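The tests of exchanged libraries, of splits and labellings that keep same-numbered libraries apart (the removal of the average genotype effect after the shares without it were seen), of leukocyte share (with its condition of a permutation p for each list) and of pancreas tissue were chosen after the values were seen, as was the comparison of the clock genes with the control groups; the other tests were set before.

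Dnm1l was not called lower in the libraries labelled knockout, although the gene was to be deleted in these livers. An exchange of some libraries of a diet would leave another split of the 8 libraries with more genes past the threshold than the labelled one, if expression follows the genotype; the highest other count was 20 against 1544 on control diet and 170 against 1310 on ethanol, which argues against it. An exchange of all libraries of 1 diet alone would set the genotype effects of the diets against each other, if the genotype acts alike on both, and their correlation of 0.599 argues against it. An exchange of all libraries of both diets cannot be told apart here, since the 95% interval of the fold of Dnm1l on control diet, up to 1.13, includes 1. A deletion of part of the gene that leaves reads over the rest cannot be told apart from an intact gene here, because the values are totals per gene; the lower 95% limit of the fold on control diet was 0.828, and no biological explanation was tested.

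Interferon-stimulated genes and leukocyte markers were both higher in the libraries labelled knockout, and a larger share of leukocytes could carry part of the interferon-stimulated rise. On control diet the mean log2 rise of the interferon-stimulated genes was 2.22 and that of the Kupffer cell, monocyte-derived, T and NK cell and B cell lists 0.91, 1.06, 1.52 and 0.82; the smallest excess, over the 6 T and NK cell genes, was 0.70 ± 0.34 (SE; exact two-sided permutation p = 0.143). On ethanol the rise was 2.49 against 1.75, 1.46, 1.70 and 1.24, with a smallest excess of 0.73 ± 0.20 (SE) over the Kupffer cell list, while the excess over the T and NK cell list had an exact two-sided permutation p = 0.0571. The rise exceeded the other 3 lists on each diet (exact two-sided permutation p = 0.0286 for each, the smallest possible). On ethanol these permutations did not keep same-numbered libraries apart, so their p-values ignore the pairing read from the numbers. The B cell list had a mean log2 value of 4.816 in control library 3 labelled knockout, below the wild-type control libraries (4.871 to 5.279). The T and NK cell genes are few, and they include the chemokine gene Ccl5, which is also on the inflammation list. Ccl5 rose by 3.65 on control diet and 3.83 on ethanol (log2). A larger share of leukocytes therefore cannot be told apart from a rise within cells, and the labelled genotype stays open, untested.

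Libraries 1 and 2 differed from 3 and 4 alike in both ethanol groups, with a correlation of 0.33 across 13256 genes between genotypes, against -0.08 in the control groups. Pancreas tissue in library 1 labelled knockout is argued against, since the correlation was 0.34 without that library. Collection at another time of day is a candidate explanation: the 18 clock genes differed more between these libraries than random lists matched on expression, at percentiles of 100 in wild type and 98.1 in the libraries labelled knockout, and 16 of 18 moved the same way in both. Both percentiles met the bound of 95 set for this explanation beforehand. The same list reached percentiles of 97 and 94.8 in the control groups, where the libraries did not differ alike. The bound was therefore too weak to single out the ethanol groups. The percentiles ignore direction. With direction, the differences of the clock genes correlated at 0.91 between the genotypes on ethanol, against 0.33 over all genes. That correlation was not taken for the clock genes in the control groups, so time of day cannot be told apart from other differences between these libraries. Acute-phase genes were higher by 1.99 and 0.85 (mean log2) in libraries 1 and 2 of the genotypes, and no biological explanation was tested.

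The 8 libraries of a contrast have 35 splits into groups of 4. For the genotype on control diet only the real one gave as many genes (1544, highest other split 20). The same held for ethanol in wild type (5032, highest other 14) and in the libraries labelled knockout (2543, highest other 1). A count of 1 of 35 each argues against chance as their source. It is also the smallest share these splits can give, so chance cannot be excluded. For the genotype on ethanol the count of such splits was also 1 (1310 genes), and the highest other called 170 genes, from the split of libraries 1 and 2 against 3 and 4, which points to a structure of the samples. A split of wild-type ethanol libraries 1, 2 and 4 with ethanol library 2 labelled knockout against the rest called 163. The 170 genes alone therefore do not single out libraries 1 and 2 against 3 and 4. Since the numbers met the bound for pairing, though other numbers within libraries 1 and 2 and within 3 and 4 correlated at 0.1 to 0.2 as well, the real split was compared with the 8 that part all 4 pairs, too few for a share under 0.05; the highest other of these called 0, and the others exchange genotypes within pairs. For the difference of the ethanol effects 2 of 100 random labellings gave as many as 46 genes, the real one included. The other called 1091 genes and exchanged the labels of all ethanol libraries, so that the genotype effect enters the difference. The next called 14. Where labels are mixed within a diet, the genotype effect adds to the spread within groups, so this share does not decide about chance. Of 100 labellings that keep same-numbered ethanol libraries apart 7 did so, the real one included (highest other 1091), and with the replicate block 5 of 100 gave as many as its 24 genes (highest other 1196), but in each of the others the labels of 1 diet were all kept or all exchanged, so that the genotype effect of that diet enters the difference and these shares do not decide about chance. After the average genotype effect of each gene was removed, only the real one of the same 100 labellings gave as many genes. The removal leaves the real counts as they are. The count of labellings was 1 without the block (highest other 1) and with it (highest other 14). Since this removal was chosen after the shares without it were seen, it argues against chance as the source but cannot exclude it.

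In 24 of 460 groups of 4 libraries over the genes drawn up for the text, not all named in the report, 1 library stood apart on the log2 scale, with a gap to the nearest other library, as a share of the group's range, above Dixon's 95% critical value; chance does so in about 1 in 20 groups. With that share of the range, these were labelled-knockout control library 1 for Vldlr (0.83) and Hcn3 (0.96), labelled-knockout control library 3 for Cxcl9 (0.85), Cyp26a1 (0.92) and Hsd3b2 (0.83), labelled-knockout control library 4 for Oasl2 (0.90) and H2-D1 (0.92), labelled-knockout ethanol library 2 for Irf7 (0.88) and Por (0.83), labelled-knockout ethanol library 3 for Gdf15 (0.95). The others were wild-type control library 2 for Mup20 (0.85), Psat1 (0.87), Abcc4 (0.90) and Ifi27l2a (0.92), wild-type control library 3 for Acly (0.91) and Pltp (0.94), wild-type control library 4 for Slc7a11 (1), wild-type ethanol library 1 for Mpeg1 (0.92) and Abcc4 (0.95), wild-type ethanol library 2 for Mdm2 (0.88), Fads1 (0.84) and Mmp12 (0.84), wild-type ethanol library 3 for Col4a1 (0.85) and Ifi44 (0.88). Among mean scores of lists, 8 of 112 groups did so: labelled-knockout control library 3 for antigen presentation list (0.97), labelled-knockout ethanol library 1 for pancreas list (0.97), labelled-knockout ethanol library 3 for cholesterol synthesis list (0.83), wild-type control library 2 for DNA sensing list (0.86), wild-type control library 3 for lipogenesis list (0.91), wild-type ethanol library 1 for monocyte-derived list (0.85), wild-type ethanol library 2 for pancreas list (0.85), wild-type ethanol library 4 for PPARA target list (0.83).

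The ethanol effect differed between the genotypes, by limma's test of the difference at the 0.05 threshold, for Nqo1 (-1.65), Cbr3 (-5.15), Cdkn1a (-3.53), Cyp2b10 (-3.74), Cyp2a5 (-2.79), Cyp26a1 (-4.28), Orm3 (-2.57), Gstm3 (-2.66), Abcc4 (-2.16) and Gsta2 (-2.97), where it was lower on the log2 scale in the libraries labelled knockout, and for Ppara (1.57), Lyz2 (1.54), Cx3cr1 (2.15), Ifi27l2a (1.89), C6 (1.59), Pltp (1.89) and Elovl2 (1.31), where it was higher. The means of the genes with a higher effect all fell with ethanol in wild type. For them a higher effect is a smaller fall or none. With the replicate block the calls of Cdkn1a, Cyp26a1, Orm3, Ppara, Lyz2, Cx3cr1, C6 and Pltp were lost (limma adjusted p from 0.0561 to 0.0739). By camera at the preset correlation it differed for the lists integrated stress response (-0.61), unfolded protein response (-0.36), fatty acid oxidation (0.18), xenobiotic cytochrome P450 (-0.71), NRF2 target (-0.90), interferon-stimulated (0.26), acute-phase (-1), male-biased liver (0.53), Kupffer cell and macrophage (0.83), endothelial (-0.22) and pancreas (2.51), given as median differences; the pancreas list rests on ethanol library 1 labelled knockout. With an estimated correlation none of these lists passed (adjusted p = 0.318 or above). Without single libraries 3 lost their call: the interferon-stimulated list without wild-type ethanol library 2 or 4, control library 3 or ethanol library 3 labelled knockout (adjusted p from 0.113 to 0.151), the male-biased list without wild-type control library 1 or 4, wild-type ethanol library 3 or 4, control library 1 or ethanol library 2 or 4 labelled knockout (0.0504 to 0.365), and the endothelial list without wild-type control library 1 or 4, wild-type ethanol library 3 or 4, control library 2 or 4 or ethanol library 1 or 4 labelled knockout (0.0519 to 0.222).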

How the results depend on the processing

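The comparisons with TMM factors, without ethanol libraries 1 and 4 labelled knockout, with parts of the ethanol groups and with a block in the ethanol groups only were chosen after seeing the data. The genes drawn up for the text, not all of which are named there, had 185 calls over the 5 contrasts, and none of these changed direction under any alternative. In 4 cases the median of a called list changed sign as its call was lost: at the floor of 50, the proliferation and monocyte-derived lists for the genotype on ethanol (-0.126 and -0.061, from 1.203 and 2.145), and without ethanol libraries 1 and 4 labelled knockout, the proliferation list for ethanol in those libraries (0.029, from -0.486). The fourth was the unfolded protein response list for the difference with ethanol libraries 3 and 4 alone (0 after rounding, from -0.363). The 185 calls of genes all held under the pseudocount of 0.25, DESeq2 and TMM factors. Of these calls 2 were lost under the pseudocount of 4, 6 with edgeR, 10 without the trend, 9 with the replicate block, 2 without a filter, 2 of 168 with only the groups compared and 1 of 173 at the floor of 50. With fewer ethanol libraries 30 of 144 were lost with libraries 3 and 4, 24 of 98 without libraries 1 and 4 labelled knockout and 8 of 144 with libraries 1 and 2. Leaving out single libraries ended 12 of 17 calls for the difference of the ethanol effects (all but Nqo1, Abcc4, Cbr3, Cyp2a5 and Cyp2b10), 2 of 41 for the genotype on control diet (Mki67 and Scd1), 1 of 43 for the genotype on ethanol (Cux2), 1 of 38 for ethanol in the libraries labelled knockout (Dnm1l) and 0 of 46 for ethanol in wild type. Called lists that lost their call under at least 1 alternative, the estimated correlation left aside, were 8 of 23, 8 of 21, 4 of 18, 7 of 21 and 4 of 11 for the 5 contrasts, 7, 5, 2, 7 and 3 of them without 1 library.

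Without 1 library the genotype on control diet gave 922 to 1691 genes, the genotype on ethanol 848 to 1685, ethanol in wild type 4251 to 5289, ethanol in the libraries labelled knockout 1745 to 2947 and the difference of the ethanol effects 8 to 215. The limits that moved by over 1.5 times came without wild-type control library 4 (922), wild-type ethanol library 1 (857) and labelled-knockout ethanol library 3 (848), and for the difference without wild-type control libraries 1, 2 and 4 (18, 22 and 25), wild-type ethanol libraries 1, 2 and 3 (19, 12 and 215), labelled-knockout control libraries 1, 2 and 4 (29, 19 and 28) and labelled-knockout ethanol libraries 1, 2 and 4 (8, 16 and 9). The cause was not tested. The log2 fold of Dnm1l ranged from -0.111 to 0.033 on control diet, above 0 only without control library 3 labelled knockout (adjusted p 0.599 to 0.959) and from 0.023 to 0.149 on ethanol (adjusted p 0.515 to 0.929). The correlation of the genotype effects ranged from 0.543 to 0.620 and that of the ethanol effects from 0.737 to 0.773. Called lists ranged from 20 to 26, 19 to 24, 18 to 23, 18 to 24 and 9 to 14 for the 5 contrasts.

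For the difference, 46 genes in the main test became 16 without the trend, 30 with edgeR, 270 with DESeq2 and 24 with the replicate block; the cause was not tested. The replicate block gave 1228 genes for the genotype on ethanol and 1508 when only the ethanol groups were blocked, and changed no call of a named gene or list there. For the other contrasts the same-numbered correlations were -0.075 to 0.035 (genotype on control diet), -0.125 to -0.025 (ethanol in wild type) and -0.07 to 0.036 (ethanol in the libraries labelled knockout), and the block gave 1430, 4911 and 2440 genes; 2, 0 and 1 of 4 libraries correlated best with their own number, and 3 of 4 for the genotype on ethanol.

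Without ethanol libraries 1 and 4 labelled knockout the counts were 496 (genotype on ethanol), 1003 (ethanol in those libraries) and 0 (difference). With libraries 3 and 4 of the ethanol groups they were 434, 3164 (ethanol in wild type), 1370 and 0, and with libraries 1 and 2 the difference gave 264 and the correlations were 0.465 and 0.699; all of these use fewer samples. For the difference limma gave 1210 and 925 genes at an unadjusted p under 0.05 where it called 0, and edgeR called 0 and 5. Without a filter the correlations were 0.431 and 0.576 over a larger set of low genes, and 28 lists passed for ethanol in wild type. With an estimated correlation 3, 4, 0, 0 and 0 lists passed; the cause was not tested. Rescaling by median-of-ratios factors was not run, since those are the factors of the file. At the depth, spread and number of these libraries 26.9% of simulated 2-fold changes were recovered for the difference of the ethanol effects, the lowest share of the 5 contrasts; depth alone was not varied.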

Other observations

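Sex-biased liver genes moved with ethanol although all 16 libraries had the expression pattern of males. In wild type 8 of 16 male-biased genes fell and 1 rose with ethanol, and 5 of 6 female-biased genes rose, 9 and 1, and 5, adjusted over the list alone (camera adjusted p = 0.00138 and 0.0115, but adjusted p = 0.467 and 0.430 with an estimated correlation). The steroid dehydrogenase gene Hsd3b5 (chromosome 3, 98618634 to 98630252 in GRCm38) went from 3040 ± 951 to 22.1 ± 12.6 normalised reads (SD, n = 4), the organic anion transporter Slco1a1 was at a fold of 0.0877 (limma adjusted p = 0.000218), and Cux2, a female-biased transcription factor, rose from 4.60 ± 2.33 to 209 ± 224. With ethanol libraries 1 and 2 alone the call of the female-biased list was lost (adjusted p = 0.0634). On ethanol Cux2 was at a fold of 0.105 in the libraries labelled knockout against wild type (limma adjusted p = 0.0134), a call lost without ethanol library 1 or 4 labelled knockout (adjusted p = 0.0512 and 0.0533) with only the groups compared (adjusted p = 0.0707), with ethanol libraries 1 and 2 alone (adjusted p = 0.139) and without both of ethanol libraries 1 and 4 labelled knockout (adjusted p = 0.266). Wild-type ethanol library 4 had 6140 normalised reads of the female-biased Cyp2b9, against 454 or fewer in the other libraries. On ethanol the male-biased Cyp4a12a and Mup20 were 5.99-fold and 5.03-fold higher in the libraries labelled knockout than in wild type. Their means were also higher there on control diet, at 3571 and 45250 normalised reads against 2081 and 24520. Those of Hsd3b5 and Slco1a1 on ethanol were 14.97 and 1229, against 22.13 and 1204 in wild type. Both genes had lower means on control diet, at 766.3 and 4753 against 3040 and 9486. The mean log2 value of the male-biased list on ethanol was 9.407 to 10.08 against 8.476 to 9.509, so the groups overlapped.

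The clock output genes Dbp, Tef and Nr1d2 and the alcohol dehydrogenase gene Adh4 fell in wild type, while the clock list as a whole did not pass the threshold. Dbp was at a fold of 0.134, Tef at 0.480 and Nr1d2 at 0.489 after ethanol (limma adjusted p = 9.62e-05, 6.03e-06 and 3.12e-05), with 8 of 18 clock genes lower and 4 higher, 8 and 5 adjusted over the list alone (camera adjusted p = 0.441). The means of Dbp, Tef and Nr1d2 also fell in the libraries labelled knockout, from 816 to 191, 2247 to 1424 and 1241 to 762 normalised reads. Adh4 went from 1820 ± 82.0 to 392 ± 57.0 in wild type and from 1739 ± 501 to 515 ± 30.2 in the libraries labelled knockout (SD, n = 4). Immediate early and heat shock genes rose for 10 of 17 in wild type and 8 of 17 in the libraries labelled knockout, 10 in each adjusted over the list alone, with Myc at 8.39-fold in the former and Fos at 7.65-fold in the latter (camera adjusted p = 0.000586 and 0.000406, but adjusted p = 0.349 and 0.311 with an estimated correlation).

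Ethanol library 1 labelled knockout had 1229 normalised reads of Prss2, 2563 of Ctrb1 and 968 of Cpa1, genes of pancreatic acinar cells that had 5 or fewer in every other library. Of the fat genes, Adipoq had 18 in ethanol library 4 and 10 in ethanol library 1 labelled knockout and 0 in the others, and Cfd had 120 in that library 4, 69 in wild-type control library 3 and 22 or fewer in the others. Ethanol library 4 labelled knockout had 1506 of the globin gene Hba-a1. The acute-phase gene Saa1 had 66698 and 49001 normalised reads in wild-type ethanol libraries 1 and 2 against 462 and 1104 in libraries 3 and 4, and 38416 in control library 3 labelled knockout against 1787 to 2667 in the other libraries of that group.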
